A study of Mus musculus with 4 samples.

How the data were processed

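RNA was measured by sequencing in 4 libraries of primary mouse cortical astrocytes, 2 wild-type (WT) and 2 CD38 knockout (CD38 KO). Per the labels' protocols, cortices of pups aged 1 to 3 days were dissociated with dispase and grown for 14 days in medium with 10% serum. Flasks were then shaken for 12 h, the liquid was thrown away, and the attached cells were replated and harvested 5 days later. Libraries were stranded and selected for polyA RNA, per the same protocols. The submitters' processing notes name bcl2fastq 2.17, STAR 2.7.0f, Cufflinks 2.2.1 and the genome build GRCm38. Per the file headers, the deposited values are FPKM per gene (fragments scaled to transcript length and to all mapped fragments), 1 value for each of 55467 Ensembl gene IDs in every library. The release of the gene annotation and any scaling between libraries are not given in the sources used here. Positions and gene classes were taken from GENCODE M21 on GRCm38, which matched 55226 of the IDs and left 241 unmatched.

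Depth is not stated in the files and was recovered from the values. In 17493 genes with a single annotated transcript longer than 600 bases, low FPKM values fall on steps of 1 fragment, and the step size gives the total. Below 10 fragments, 91.8% to 92.4% of values fell within 0.1 of a whole number of fragments. The estimate was 26843551 and 28292442 fragments for WT 1 and WT 2 and 29064225 and 29099502 for CD38 KO 1 and CD38 KO 2. On simulated values of known depth it was exact. Those values were made with the same step rule that the fit assumes, so they do not show its accuracy on these files. Intervals built on these fragments cover counting error only.

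Genes with a mean of at least 1 FPKM over the 4 libraries were tested, 13064 in all, and Cd38 was to be kept whatever its level. The test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with genotype as the only term, empirical Bayes moderation with a trend, and Benjamini-Hochberg adjustment over all tested genes at 0.05. A gene is called when it passes this threshold, and fold changes in FPKM are ratios of group means without the added 1. A test on counts was not run, since the values are not counts. In 5 simulations with 13064 genes, 2 libraries against 2 and 200 changed genes each, the fit recovered 46.6% of changes of 0.5 on the log2 scale, 85.5% of changes of 1 and 98.6% of changes of 2. False calls made up 4.75% of calls, and simulations with no change gave 0 calls. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

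The tests, the gene lists, the rule for naming genes and most of the alternatives were chosen before the data were examined. The rule named Cd38 and Sparcl1, and the 10 largest increases and 10 largest decreases in log2(FPKM + 1) among called genes with an official symbol and both libraries of one genotype above both of the other. Pseudogenes and genes named by a Gm number or Rik were left out of that ranking, whatever their change. The pseudogenes named in the report lie outside this rule and were chosen after their values were seen. It also named up to 4 members of each list, those of smallest p. Where a count of 5 or fewer holds genes outside this rule, they are named too, and were chosen after their values were seen. The 35 lists cover pathways and cell types, with 853 of their 855 distinct genes in the files; where a symbol stood on more than 1 ID, as 113 symbols did, the ID of highest mean FPKM was used. Each list was compared with the other tested genes by camera in limma, two-sided, with a preset correlation between genes of 0.01 and adjustment over the 35 lists, all of which had at least 3 tested genes. The simulations recovered a list shifted by 0.5 in 5 of 5 runs, and camera called no other list in them. Camera with an estimated correlation and camera on ranks were run as alternatives. So was fry, which answers another question, whether a list changed at all, and the ranges over a list's alternatives include it. Genes within 10 Mb of Cd38 were compared with all other tested genes by Fisher's exact test, two-sided.

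Alternatives for the gene tests were other values added before the log, 0.1 and 0.5, no filter, a filter at 5 FPKM, quantile normalization, median-of-ratios scaling, replicate number as a block, moderation without trend or robust, a 2-fold limit, no test, and each library left out in turn. In a fit with 1 library left out, the lone library of its genotype is assumed to vary like the other genotype. Further alternatives were chosen after seeing the data, namely protein-coding genes only, a block that crosses the replicate numbers, lists without genes shared with the microglia list, and the test around Cd38 without Cd38 itself or under each of the settings above.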

Results

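RNA from cultures of astrocytes, the main supporting glia of the brain, was compared between WT and CD38 KO mice with 2 libraries of each genotype. CD38 is a cell-surface enzyme that consumes NAD+ and makes messengers that release calcium from stores. The series asks what CD38 in astrocytes of the young brain does for the forming of synapses and for social memory later in life, and this comparison asks which astrocyte transcripts differ without Cd38. The libraries held an estimated 26843551 and 28292442 fragments in WT and 29064225 and 29099502 in CD38 KO. Across genes, Pearson's r was 0.990 between the WT libraries, 0.985 between the CD38 KO libraries and 0.964 to 0.968 between genotypes. Genes are not independent replicates, so these correlations carry no p. The SD of the log2 difference between libraries was 0.258 within WT and 0.309 within CD38 KO, against 0.455 to 0.482 between genotypes. The labels do not say whether replicates are separate animals or cultures, and p-values then measure only the spread between these samples, which can be technical.

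Cd38 transcripts were close to absent from both CD38 KO libraries. Cd38 (ENSMUSG00000029084, GRCm38 chromosome 5, 43868553 to 43912375) was at 3.13 and 3.45 FPKM in WT and at 0.0222 FPKM in each CD38 KO library. These values stand for 261 and 303 fragments in WT and 2 fragments in each CD38 KO library. Corrected for depth, the CD38 KO level was 0.672% of the WT level (95% interval 0.183% to 1.73%, exact Clopper-Pearson), which is 149-fold lower (57.8 to 548). The limma log2 change was -2.07 (SE 0.13, n = 2 and 2, adjusted p = 0.000575). Cd38 stayed called in all 4 fits without 1 library (adjusted p up to 0.014). All 4 libraries thus carried the Cd38 level their labels name, although the labels do not give the deleted exons.

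Between the genotypes, 1045 genes were higher and 830 genes lower in CD38 KO among 13064 tested, 14.4% in all. Of these, 259 higher and 101 lower genes changed at least 2-fold in log2(FPKM + 1). Protein-coding genes made up 988 of the higher and 752 of the lower genes. The strains are not given in the labels. In these counts and in the lists below, loss of Cd38 therefore cannot be told apart from a strain difference between the genotypes. The 1875 called genes all had both libraries of one genotype above both of the other. This separation was seen in 7821 tested genes, 59.9%, where chance gives 33.3%, and 3955 genes had an unadjusted p under 0.05. With fewer libraries fewer genes were called, namely 458 higher and 284 lower without WT 1, 407 and 252 without WT 2, 306 and 241 without CD38 KO 1, and 342 and 225 without CD38 KO 2.

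**Figure D1:**
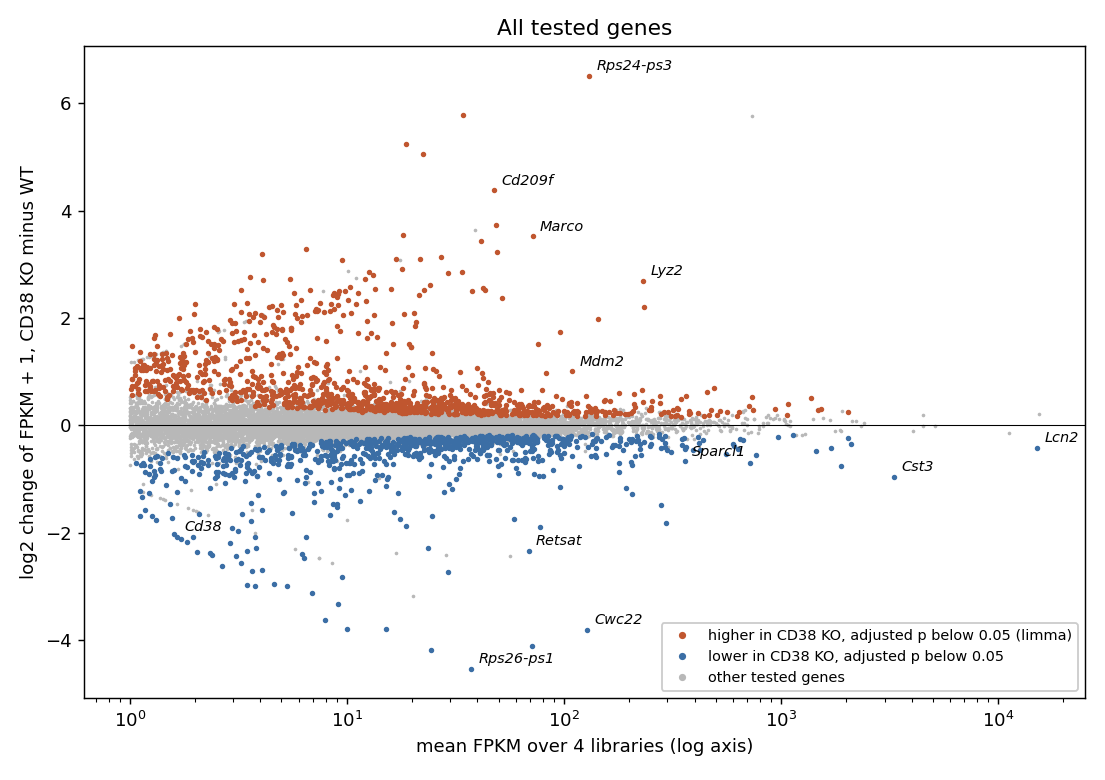
Log2 change of FPKM + 1 (CD38 KO minus WT, vertical axis) against mean FPKM over the 4 libraries (horizontal log axis) for the 13064 tested genes, with the 1045 called higher and the 830 called lower by limma in colour. Cd38 lies at -2.07, Sparcl1 at -0.66 and Lyz2, a macrophage lysozyme gene, at 2.69.

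With pseudogenes and genes named by a Gm number or Rik left out, the 10 largest increases were mostly genes of macrophages and other immune cells. Cd209f (ENSMUSG00000051906, chromosome 8, 4102787 to 4105835), a lectin of the DC-SIGN family, rose 26.6-fold from 3.46 ± 0.187 to 92.1 ± 6.42 FPKM (SD, n = 2 each), and its neighbour Cd209g rose from 0.405 to 12.6 FPKM. Marco, a macrophage scavenger receptor, rose from 10.7 ± 2.01 to 133 ± 9.56 FPKM, a 12.4-fold change. Cd5l, a protein secreted by macrophages, rose 15.4-fold to 91.0 FPKM, Wfdc17 12.3-fold to 76.8 FPKM and Cd52, a surface glycoprotein of leukocytes, 10.3-fold to 89.6 FPKM. Fcrls, a receptor-like protein of microglia, rose from 4.71 to 49.6 FPKM and C1qc, a chain of complement C1q, from 3.74 to 39.8 FPKM. The log2 changes of these 8 genes lay between 3.10 and 4.38, with adjusted p of at most 8.47e-05. Of the 8, Fcrls and C1qc are in the microglia and macrophage list fixed beforehand. The others were grouped with them after the ranking. The remaining places went to the small nucleolar RNA Snora20, listed at 0 in WT and at 8.13 ± 1.24 FPKM in CD38 KO, and to n-R5s193, annotated as ribosomal RNA. The latter was listed at 0 in WT and at 110 and 26.3 FPKM in CD38 KO. Its call (adjusted p = 0.00354) ended with robust moderation (0.0809) and without a filter (0.0634), within a range of 0.000599 to 0.0809 over its alternatives. Snora20 and n-R5s193 are shorter than the 167 to 170 bases that the depth fit took off transcript length. Their FPKM can therefore rest on few fragments, whose number was not recovered.

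Among the 10 largest decreases, again without pseudogenes and Gm or Rik names, Cwc22 (ENSMUSG00000027014, chromosome 2, 77881159 to 77946375), a splicing factor whose copy number is known to differ between mouse strains, fell 14.9-fold from 240 ± 36.3 to 16.1 ± 0.337 FPKM (SD, n = 2 each). The protease inhibitor Serpina3m fell from 19.6 to 0.485 FPKM, and Cnmd, which encodes the cartilage protein chondromodulin, from 29.2 to 1.17 FPKM. Gbp10, an interferon-induced GTPase, fell 24.6-fold to 0.417 FPKM, and Ly6a, the surface antigen Sca-1, fell 7.49-fold to 6.90 FPKM. Retsat, which saturates retinol, fell 5.21-fold from 115 to 22.2 FPKM, and Angptl4, a secreted inhibitor of lipoprotein lipase, 10.9-fold to 0.641 FPKM. The others were Abhd1 and AA465934, which the annotation lists as processed transcripts, down 8.53-fold and 9.10-fold, and the small nucleolar RNA Snora64, at 4.14 and 4.06 FPKM in WT and listed at 0 in CD38 KO. Snora64 is also shorter than the length taken off in the depth fit, so its FPKM can rest on few fragments. The log2 changes of these 10 genes ran from -3.81 to -2.28, with adjusted p of at most 0.00254. Each of the 20 genes of both groups was also called in all 4 fits without 1 library, while AA465934 lost its call without a filter (adjusted p = 0.0526, range over its alternatives 0.00157 to 0.0526).

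**Figure D2:**
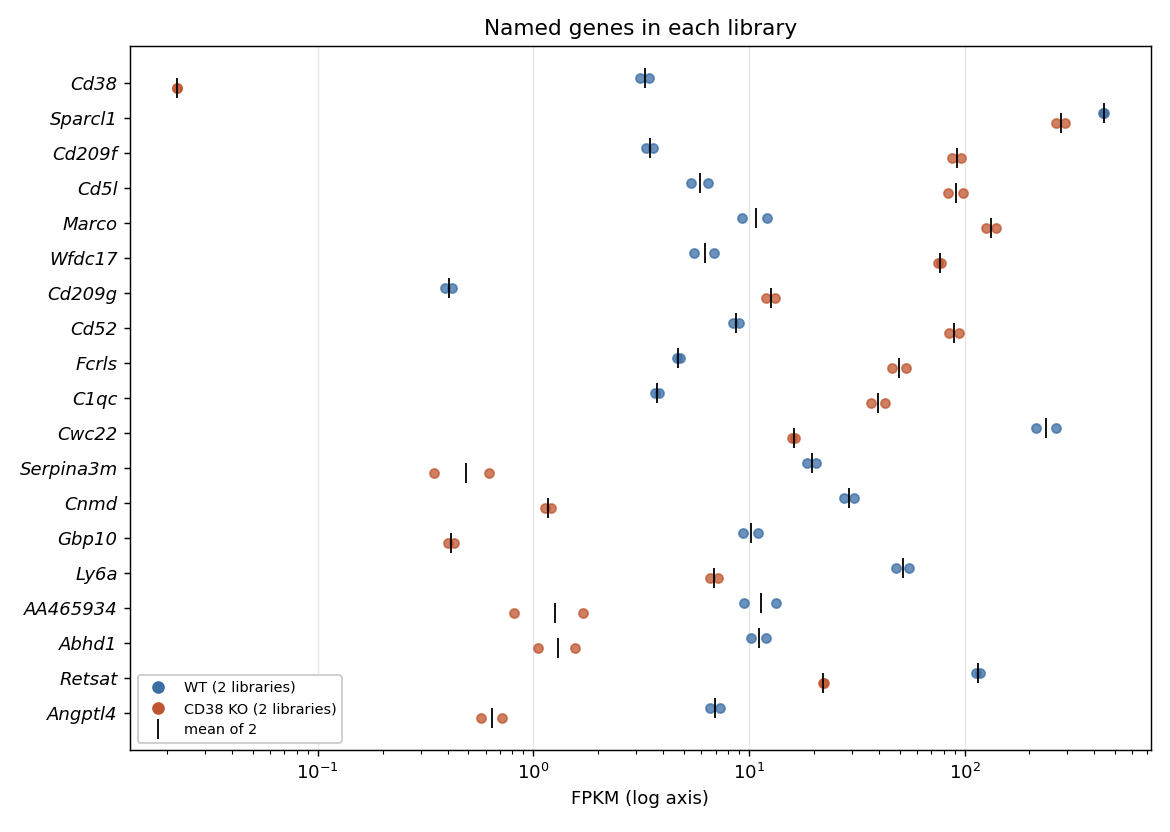
FPKM (log axis) of Cd38, Sparcl1 and 17 of the 20 genes with the largest changes (pseudogenes and Gm or Rik names left out) in each library, with WT and CD38 KO dots and a bar at each mean of 2 libraries; Snora20, Snora64 and n-R5s193, listed at 0 in one genotype, are not drawn. In every gene shown the 2 libraries of one genotype lie above the 2 of the other, as for Marco at 10.7 and 133 FPKM.

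Sparcl1, which encodes hevin, a protein that astrocytes secrete and that promotes synapses, was lower in CD38 KO. Sparcl1 (ENSMUSG00000029309, chromosome 5, 104079111 to 104113733) fell from 442 ± 3.22 to 279 ± 20.3 FPKM (SD, n = 2 each), a 1.58-fold decrease (log2 change -0.66, SE 0.06, adjusted p = 0.0019). It was called in all 4 fits without 1 library, with log2 changes of -0.74 to -0.59. The wider list of astrocyte-secreted synapse regulators went both ways, with 4 of 23 tested members higher and 8 lower (4 and 10 adjusted over the list alone). Beside it, the microglia and macrophage list described below had a median log2 change of 2.31. Which cells in the cultures made the transcripts of the higher members was not tested. Tnr, the matrix protein tenascin-R, fell from 13.6 to 4.32 FPKM and Tgfb1, transforming growth factor beta 1, rose from 2.35 to 7.14 FPKM, and these with Sparcl1 were the 3 members called in every fit without 1 library. The other higher members were the growth factor Bdnf, the engulfment bridge Pros1 and the proteoglycan Vcan, whose calls ended without WT 1, CD38 KO 1 and CD38 KO 2 (adjusted p up to 0.0916, 0.091 and 0.177). As a set the list was not called by camera (adjusted p = 0.123, median log2 change -0.03, and -0.12 to -0.04 in the fits without 1 library). It passed at a filter of 5 FPKM (0.0415) and without CD38 KO 2 (0.0306), within a range of 0.0306 to 0.553 over its alternatives.

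Camera called 12 of the 35 lists, and 8 to 16 in the fits without 1 library. With an estimated correlation between genes it called 0, also at an unadjusted p under 0.05, while fry, which tests a list against no change and not against the other genes, called 17 lists, 11 of them among the 12. The estimated correlation rests on the spread within 2 libraries against 2, which leaves camera little power. It gave adjusted p = 0.421 even to the microglia and macrophage list, and the same value to the p53 and cell cycle lists. A call that ended with it therefore cannot tell a weak list from a strong one. The camera calls below rest on the preset correlation, which these data cannot check.

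**Figure D3:**
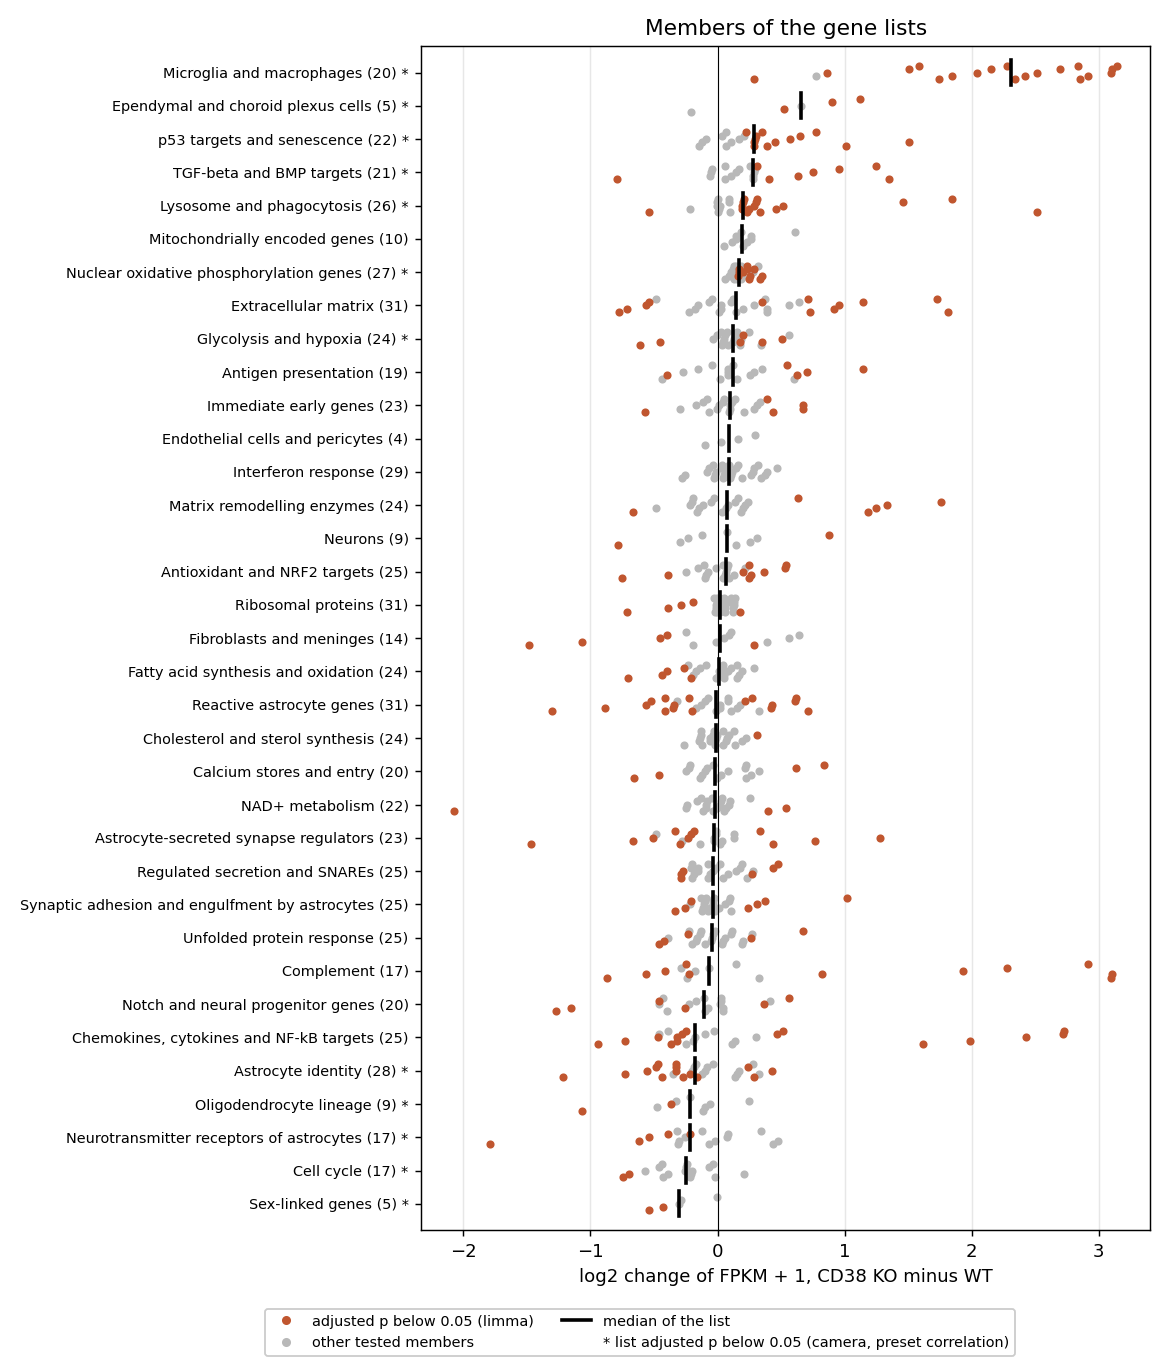
Log2 change of FPKM + 1 (CD38 KO minus WT) of each tested member of the 35 lists (dots, coloured where limma called the gene), with black bars at list medians, the number of tested members after each name and a star where camera called the list. The microglia and macrophage list stands farthest from 0, with a median of 2.31.

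Genes of microglia and macrophages, the resident phagocytes of the brain and their relatives, were higher in CD38 KO almost throughout the list. Of 20 tested members 19 were called higher (20 adjusted over the list alone), with a median log2 change of 2.31. Fcer1g, a signalling subunit of Fc receptors, rose from 7.55 ± 1.05 to 60.4 ± 1.61 FPKM (SD, n = 2 each), C1qb from 2.74 to 31.1 FPKM and C1qc from 3.74 to 39.8 FPKM. Lyz2, picked after its values were seen as the most abundant member, rose from 61.4 ± 7.23 to 402 ± 37.7 FPKM. Without 1 library 17 or 18 members were called, and the microglial marker Tmem119 lost the call in all 4 such fits (adjusted p up to 0.167). The list was called by camera (adjusted p = 8.89e-23). That call ended with adjusted p = 0.421 with an estimated correlation, the highest of a range from 5.4e-24 over its alternatives.

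Lysosomal genes were also higher, with 15 of 26 tested members called higher and 1 lower (15 and 2 adjusted over the list alone) and a median log2 change of 0.20. Gpnmb, a glycoprotein of lysosomes in phagocytes, rose from 10.0 to 29.3 FPKM and Ctsz, a cathepsin, from 128 to 177 FPKM, while Glb1, beta-galactosidase, was the lower member at a log2 change of -0.54. Laptm5 and Cd68 are among the members shared with the microglia list, whose median was 2.31, and without the shared members 12 of 23 were higher and 1 lower. Camera called the list (adjusted p = 1.08e-05) and also without the shared genes (0.000921), but not at adjusted p = 0.489 with an estimated correlation, with a range of 6.79e-07 to 0.489 over its alternatives. In fits without WT 1, WT 2, CD38 KO 1 and CD38 KO 2, the higher members numbered 5, 4, 4 and 4.

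Complement genes changed in both directions. Of 17 tested members 6 were higher and 5 lower (6 and 6 adjusted over the list alone). C1qa, C1qb and C1qc, shared with the microglia list, rose 9.41-fold, 11.4-fold and 10.6-fold, and the receptor C3ar1 rose from 1.93 to 13.2 FPKM. The lower members were the proteases C1s1 and C1ra, the inhibitors Serping1 and Cd59a, and C3, of which C1s1 (log2 change -0.87) alone was called in every fit without 1 library. Serping1 lost its call without CD38 KO 2 (0.0625), Cd59a without 3 of the libraries (up to 0.116), and C1ra and C3 in all 4 such fits (up to 0.126 and 0.23). The list was not called (camera adjusted p = 0.579), with a median of -0.07 (-0.22 to -0.01 in the fits without 1 library), a mean of 0.68 and an upward camera direction. Without the C1q genes 3 of 14 members were higher and 5 lower, namely C3ar1, Cd55 and C5ar1 among the higher, with a median of -0.20 and a downward direction (0.283, range over its alternatives 0.0317 to 0.905). C5ar1 lost its call without WT 1, WT 2 and CD38 KO 2 (up to 0.127).

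Chemokines and cytokines changed in opposite directions. Among 25 tested members of the chemokine, cytokine and NF-kB list 7 were higher and 8 lower (7 and 10 adjusted over the list alone). Ccl3 rose from 2.46 to 21.8 FPKM and Ccl4 from 0.702 to 10.2 FPKM, both chemokines made by myeloid cells, and Saa3, an acute-phase protein, rose from 57.1 to 230 FPKM. Ccl2, the monocyte chemoattractant, fell from 256 ± 5.87 to 154 ± 7.57 FPKM (SD, n = 2 each), and 7 of the 15 called members were called in all 4 fits without 1 library. The list was not called (camera adjusted p = 0.603, downward), with a median of -0.18 (-0.20 to -0.11 in the fits without 1 library) and a mean of 0.31, while fry gave the upward direction (0.0317, range over its alternatives 0.0317 to 0.913). Antigen presentation genes had 4 of 19 members higher and 1 lower (7 and 2 adjusted over the list alone). H2-Ab1, a class II chain, rose from 2.39 to 6.52 FPKM in this list, which was not called (camera adjusted p = 0.131). The class I genes H2-K1, H2-D1 and H2-Q7 were the other higher members and the peptide transporter Tap2 the lower one. Over all 17 tested H2 genes, in the list or not, 6 were higher and 4 lower. Outside the list, H2-T3 fell from 2.59 to 0.0518 FPKM, H2-Q10 from 5.54 to 1.07 and H2-Q2 from 9.02 to 2.22. These genes were picked after their values were seen, and the call of H2-Q10 ended without CD38 KO 1 and without CD38 KO 2. The calls of Tap2, H2-K1 and H2-Q7 ended without CD38 KO 2 (0.0565, 0.0555 and 0.0583), and those of H2-K1, H2-D1 and H2-Q7 without CD38 KO 1 (0.0868, 0.0916 and 0.124). The list as a set passed without CD38 KO 2 (0.0353, range over its alternatives 0.0353 to 0.845). In the interferon response list limma called 0 of 29 members, also adjusted over the list alone, and 7 higher and 1 lower at an unadjusted p under 0.05. That list (camera adjusted p = 0.245, median 0.09) passed upward without WT 2 (0.00798) and without CD38 KO 2 (0.00224), within a range of 0.00224 to 0.845 over its alternatives. Its median was 0.25 and 0.26 in those 2 fits but below 0 in the others, at -0.07 without WT 1 and -0.10 without CD38 KO 1. The median of the microglia list beside these 3 immune lists was 2.31.

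Some of the genes that mark astrocytes were lower. Of 28 tested members of the astrocyte identity list 3 were higher, 12 lower and 13 not called (7 higher and 15 lower adjusted over the list alone), with a median log2 change of -0.18 (-0.14 without WT 1 to -0.23 without WT 2), beside the microglia list median of 2.31. Kcnj10, the potassium channel Kir4.1, fell from 270 ± 2.27 to 184 ± 12.0 FPKM (SD, n = 2 each), and Aldoc, a glycolytic aldolase of astrocytes, from 364 ± 1.35 to 260 ± 16.8 FPKM, a call that ended with no filter (0.0536, range over its alternatives 0.00222 to 0.0536). The calcium-binding S100b fell 2.61-fold to 4.22 FPKM, a call that ended without WT 2 (0.0571). The higher members were Gpr37l1, up from 36.4 to 49.2 FPKM, Aldh1l1 and the gap junction gene Gja1, which all lost their call without CD38 KO 2 (0.0578, 0.0862 and 0.101). Camera called the list (adjusted p = 0.0103), and the call ended at adjusted p = 0.421 with an estimated correlation and without WT 1 (0.0517), within a range of 0.0041 to 0.421 over its alternatives. Lower members numbered 4, 2, 6 and 6 in the fits without WT 1, WT 2, CD38 KO 1 and CD38 KO 2.

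Receptors by which astrocytes sense transmitters were lower in 5 of 17 tested members, with 1 higher and 6 lower adjusted over the list alone. Beside them, the astrocyte identity list had a median log2 change of -0.18 and the microglia list one of 2.31. Adora2b, an adenosine receptor, fell from 6.16 to 1.07 FPKM and Ednrb, an endothelin receptor, from 48.4 to 31.2 FPKM. The receptors Adra1a, Ednra and Grik5 were the other lower members, with calls that ended in all 4 fits without 1 library (adjusted p up to 0.108, 0.158 and 0.178). Camera called the list (adjusted p = 0.0333, median -0.22, and -0.13 without CD38 KO 1), but not at adjusted p = 0.421 with an estimated correlation. It was not called either without WT 1 (0.0822), without CD38 KO 1 (0.067), at a filter of 5 FPKM (0.113) or on ranks (0.0593), and its alternatives ranged from 0.00949 to 0.421.

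Reactive astrocyte genes went both ways, with 7 of 31 tested members higher and 10 lower (9 and 10 adjusted over the list alone). Steap4, a metalloreductase induced in inflammation, fell from 658 to 457 FPKM and the proteoglycan Srgn from 14.4 to 5.28 FPKM, while the surface protein Cd109 rose from 36.1 to 55.4 FPKM, the only members called in all 4 fits without 1 library. The list was not called (camera adjusted p = 0.427, median -0.01, and -0.07 to -0.02 in the fits without 1 library). In the Notch and neural progenitor list 2 of 20 members were higher and 4 lower (2 and 8 adjusted over the list alone). Hopx, a homeodomain protein of progenitors, fell from 290 to 120 FPKM, while the receptor Tnfrsf19 rose from 18.4 to 27.8 FPKM. Egfr was the other higher member and Notch1 and Jag1 were among the lower ones, with calls of these 3 lost in all 4 fits without 1 library (adjusted p up to 0.154, 0.142 and 0.192). Camera gave that list an adjusted p of 0.0507 (median -0.10). It passed with median-of-ratios scaling (0.0497), with no filter (0.0288), with fry (0.0234) and without WT 2 (0.0384), within a range of 0.0234 to 0.421 over its alternatives.

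Nuclear genes of oxidative phosphorylation were in part slightly higher. Of 27 tested members 11 were called higher (23 adjusted over the list alone), and the other 16 were not called. Cox5a, a subunit of cytochrome oxidase, rose from 292 ± 1.16 to 369 ± 9.50 FPKM (SD, n = 2 each) and Ndufb8, a subunit of complex I, from 186 ± 5.31 to 237 ± 6.55 FPKM. The list was called by camera (adjusted p = 5.54e-09, median log2 change 0.17), though not at adjusted p = 0.421 with an estimated correlation, in a range of 8.06e-12 to 0.421 over its alternatives. The higher members numbered 2, 0, 0 and 1 without WT 1, WT 2, CD38 KO 1 and CD38 KO 2. Each member lost its call in at least 3 of the 4 fits without 1 library, Cox5a without WT 1, WT 2 and CD38 KO 1 (up to 0.0628) and Ndufb8 without WT 2, CD38 KO 1 and CD38 KO 2 (up to 0.0722). Genes encoded in the mitochondrion had 0 of 10 members called by limma, also adjusted over the list alone, and 1 higher at an unadjusted p under 0.05. Their median log2 change of 0.20 did not pass (camera adjusted p = 0.12), except without CD38 KO 1 (3.33e-05, range over its alternatives 3.33e-05 to 0.954). That median was 0.39 without CD38 KO 1, 0.25 without WT 1, 0.10 without WT 2 and 0.02 without CD38 KO 2.

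Targets of the tumour suppressor p53 were higher in 13 of 22 tested members, and the other 9 were not called (14 higher adjusted over the list alone). Pmaip1, the cell death gene Noxa, rose from 9.57 ± 0.283 to 29.1 ± 1.68 FPKM (SD, n = 2 each). Mdm2, which feeds back on p53, rose from 72.3 ± 1.37 to 147 ± 9.66 FPKM and Aen, a nuclease, from 49.4 to 78.1 FPKM. Camera called the list (adjusted p = 2.93e-06, median log2 change 0.29), with adjusted p = 0.421 with an estimated correlation and a range of 1.37e-07 to 0.421 over its alternatives. The fits without WT 1, WT 2, CD38 KO 1 and CD38 KO 2 called 7, 6, 3 and 4 members higher. Cell cycle genes were lower in 2 of 17 tested members, with 1 higher and 6 lower adjusted over the list alone. These were Top2a, a topoisomerase of dividing cells, down 1.99-fold from 4.30 FPKM, and Birc5, a mitotic regulator, down from 1.95 to 0.817 FPKM, and both lost their call in all 4 fits without 1 library (adjusted p up to 0.101 and 0.107). Camera called the cell cycle list (adjusted p = 0.00301, median -0.25), and the call ended at adjusted p = 0.421 with an estimated correlation. At a filter of 5 FPKM it was 0.504, and the alternatives ranged from 2.21e-07 to 0.504.

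Targets of TGF-beta and BMP signalling were higher in 7 of 21 tested members and lower in 1 (9 and 1 adjusted over the list alone). Ltbp2, which binds microfibrils in the matrix, rose from 13.5 ± 1.34 to 35.9 ± 1.43 FPKM (SD, n = 2 each) and was called in all 4 fits without 1 library. Ltbp1 rose from 7.74 to 12.6 FPKM and Ccn2, a matricellular growth factor, from 90.5 to 120 FPKM, while Nog, the BMP inhibitor noggin, fell from 11.3 to 6.14 FPKM. Those 3 calls ended without WT 2 (0.0542, 0.0699 and 0.0605), and without WT 1, WT 2, CD38 KO 1 and CD38 KO 2 the higher members numbered 3, 2, 2 and 2. Camera called the list (adjusted p = 0.00395, median 0.28), with adjusted p = 0.421 with an estimated correlation and a range of 0.00154 to 0.421 over its alternatives. The median was 0.24 without WT 1, 0.27 without WT 2, 0.16 without CD38 KO 1 and 0.37 without CD38 KO 2. Matrix genes were higher in 8 of 31 tested members and lower in 4 (11 and 7 adjusted over the list alone). Postn, periostin, rose from 1.90 to 9.20 FPKM, Col11a1 from 4.66 to 11.5 FPKM and the basement membrane gene Nid2 from 20.7 to 34.9 FPKM. The crosslinking enzyme Loxl1 fell from 24.4 to 16.5 FPKM, beside Col6a1, Col6a2 and Lama4, whose calls ended without WT 2 and CD38 KO 2 (adjusted p up to 0.0658, 0.1 and 0.102). The matrix list was not called (camera adjusted p = 0.251), except without CD38 KO 2 (0.0326, range over its alternatives 0.0326 to 0.845). Matrix remodelling enzymes had 5 of 24 members higher and 1 lower (7 and 6 adjusted over the list alone). Ctsl, cathepsin L, rose from 358 to 554 FPKM, and Mmp12, Plau and Mmp9, proteases that macrophages secrete, rose to 3.47, 2.91 and 2.27 FPKM from 0.329, 0.725 and 0.305 FPKM, beside the microglia list median of 2.31. Timp4 was the lower member, with a call that ended without WT 1, WT 2 and CD38 KO 1 (adjusted p up to 0.118). Camera did not call these enzymes (adjusted p = 0.322), while fry did (0.0345, range over its alternatives 0.0345 to 0.845).

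NAD+ metabolism, the pathway that holds CD38, changed in few genes besides Cd38. Of 22 tested members 2 were higher and 1, Cd38, was lower (2 and 1 adjusted over the list alone). Sirt3, a mitochondrial NAD+-dependent deacylase, rose from 23.7 ± 0.602 to 31.5 ± 1.02 FPKM (SD, n = 2 each) and Nmnat2, an NAD+ synthase, from 3.21 to 5.10 FPKM, though both lost their call in all 4 fits without 1 library (adjusted p up to 0.0868 and 0.103). Nampt, the rate-limiting enzyme of NAD+ salvage, was at 60.3 FPKM in WT and 53.8 in CD38 KO (adjusted p = 0.0772). The list was not called (camera adjusted p = 0.757). Genes of calcium stores and entry had 2 of 20 members higher and 2 lower (6 and 3 adjusted over the list alone). Atp2b4, a plasma membrane calcium pump, fell from 42.3 to 26.5 FPKM and Calr, the store protein calreticulin, from 490 to 356 FPKM. The pump Atp2b2 and the channel Trpm2, which ADP-ribose opens, rose from 1.82 to 3.34 and from 0.639 to 1.91 FPKM, with calls lost without WT 1, CD38 KO 1 and CD38 KO 2 (adjusted p up to 0.115 and 0.126). Camera did not call the calcium list (adjusted p = 0.753, downward), whose median was -0.02 (-0.04 to 0.01 in the fits without 1 library) and mean 0.03.

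Genes of contact and secretion at synapses changed in both directions. For synaptic adhesion and engulfment, 4 of 25 tested members were higher and 3 lower (4 and 3 adjusted over the list alone), beside the microglia list median of 2.31. Mertk, an engulfment receptor, rose from 1.28 to 3.62 FPKM and was called in all 4 fits without 1 library. Itgb5, Gja1 and Cadm1 were the other higher members and Ezr, Mfge8 and Dag1 the lower ones, and all 6 lost the call without CD38 KO 1 and CD38 KO 2 (adjusted p up to 0.189, that of Cadm1). The list was not called (camera adjusted p = 0.588, downward), with a median of -0.04 (-0.06 to -0.02 in the fits without 1 library) and a mean of 0.02. Regulated secretion and SNARE genes had 3 of 25 members higher and 3 lower (3 and 4 adjusted over the list alone). Vamp8 rose from 15.8 to 22.4 FPKM, with Stx3 and Rab11a, while the vesicle proteins Syt11, Snap23 and Vamp3 fell, Syt11 from 153 to 125 FPKM. Those 6 calls ended without CD38 KO 1 and CD38 KO 2 (adjusted p up to 0.199, that of Rab11a), and the list was not called (camera adjusted p = 0.57, downward, median -0.04, and -0.06 to 0.02 without 1 library, mean 0.01).

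Metabolic and stress lists moved in a few members each. In the glycolysis and hypoxia list 4 of 24 members were higher and 2 lower (6 and 2 adjusted over the list alone). Ldhb, a lactate dehydrogenase subunit, rose from 1141 to 1618 FPKM, while Pfkp, a phosphofructokinase, fell from 80.6 to 52.5 FPKM. The call of Ldhb ended with no filter (0.0517, range over its alternatives 0.000589 to 0.0517). Hk2, Pfkfb3 and Gpi1 were the other higher members and Ndrg1 the other lower one, with calls lost without CD38 KO 1 and CD38 KO 2 and for the first 3 in every such fit (adjusted p up to 0.252, that of Gpi1). Camera called this list (adjusted p = 0.0281, median 0.12, and 0.08 without WT 2 or CD38 KO 1), with adjusted p = 0.845 with an estimated correlation. It was not called without WT 2 (0.289), without CD38 KO 1 (0.175), without trend (0.0523) or with fry (0.338), in a range of 0.00389 to 0.845 over its alternatives. Antioxidant genes had 7 of 25 members higher and 2 lower (8 and 3 adjusted over the list alone), with Gsta4 up from 605 to 873 FPKM, Gstp1 up from 102 to 150 FPKM and the metallothionein Mt2 down from 2372 to 1410 FPKM. The other lower member, Nqo1, lost its call without WT 1, WT 2 and CD38 KO 1 (adjusted p up to 0.0843), and that list was not called (camera adjusted p = 0.253). Fatty acid genes were lower in 5 of 24 members (2 higher and 7 lower adjusted over the list alone), led by the lipogenic regulator Srebf1, from 222 to 136 FPKM. Scd1 lost its call without CD38 KO 1 (0.0501), Fabp7 without WT 1 and WT 2 (up to 0.0662), and Fads1 and Fads2 in all 4 fits without 1 library (up to 0.142 and 0.0883). That list was not called (camera adjusted p = 0.27, downward, median 0.01, and -0.01 to 0.02 without 1 library, mean -0.06), while fry called it (0.00949, range over its alternatives 0.00949 to 0.601).

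Sterol synthesis had 1 of 24 members higher, Dhcr7, up from 11.3 to 14.2 FPKM, and 0 adjusted over the list alone, where 3 members had an unadjusted limma p under 0.05. Dhcr7 lost its call in all 4 fits without 1 library (adjusted p up to 0.146), and the list was not called (camera adjusted p = 0.965, upward, median -0.01, and -0.04 to 0.05 without 1 library, mean 0.01). Unfolded protein response genes had 2 of 25 members higher and 3 lower (3 and 5 adjusted over the list alone), with the chaperone Calr down from 490 to 356 FPKM. Atf3 and Ddit3 were higher and Asns and Pdia6 lower, with calls that ended without CD38 KO 1 and CD38 KO 2 (adjusted p up to 0.116, that of Ddit3), and camera gave an adjusted p of 0.275. Immediate early genes had 4 of 23 members higher and 1 lower (4 and 2 adjusted over the list alone). Dusp1, Atf3, Nr4a2 and Fosb were higher and Zfp36 lower, with Dusp1 up from 53.6 to 70.5 FPKM, and each lost its call without CD38 KO 1 and CD38 KO 2 (adjusted p up to 0.214, that of Fosb). That list (camera adjusted p = 0.245) passed without WT 2 (0.0498) and CD38 KO 2 (0.0281), in a range of 0.0281 to 0.845 over its alternatives. Ribosomal protein genes had 1 of 31 members higher, Rpl23, and 4 lower (1 and 4 adjusted over the list alone). Rps24 fell from 894 ± 4.37 to 547 ± 35.5 FPKM (SD, n = 2 each), while its pseudogene Rps24-ps3 rose from 1.86 to 260 FPKM. Rps2 fell from 282 to 215 FPKM while Rps2-ps10 rose from 0.366 to 44.5 FPKM. Rpl10a and Rpl3 were also lower, and they and Rpl23 lost their calls in all 4 fits without 1 library (adjusted p up to 0.0644, 0.158 and 0.182), as Rps2 did without WT 1, WT 2 and CD38 KO 2 (up to 0.0979). The ribosomal list was not called (camera adjusted p = 0.654, upward, median 0.02, and -0.01 to 0.06 without 1 library, mean -0.01).

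Markers of cell types other than phagocytes moved less. Ependymal and choroid plexus genes were higher in 3 of 5 tested members (4 higher and 1 lower adjusted over the list alone), with a median log2 change of 0.65 (0.49 without CD38 KO 1 to 0.89 without CD38 KO 2). Foxj1, a regulator of motile cilia, rose from 38.6 ± 1.17 to 55.9 ± 1.69 FPKM (SD, n = 2 each), while Pifo and Dynlrb2, up from 0.367 to 1.93 and from 1.14 to 2.95 FPKM, lost their calls without CD38 KO 1 and CD38 KO 2 (adjusted p up to 0.116 and 0.154). Camera called this list (adjusted p = 0.0453), with adjusted p = 0.421 with an estimated correlation. It was called in 6 of 16 alternatives, in a range of 0.026 to 0.421, and not without WT 1 (0.0517), CD38 KO 1 (0.0611) or CD38 KO 2 (0.0608). Oligodendrocyte genes were lower in 2 of 9 tested members (3 lower adjusted over the list alone), namely Pdgfra, the progenitor receptor, from 4.11 to 1.42 FPKM, and Olig2, 1.31-fold from 19.5 FPKM. The call of Pdgfra ended without WT 2, CD38 KO 1 and CD38 KO 2 (adjusted p up to 0.12) and that of Olig2 in all 4 fits without 1 library (up to 0.148). Camera called that list (adjusted p = 0.0333, median -0.22, and -0.16 without CD38 KO 1 to -0.25 without WT 2), with adjusted p = 0.421 with an estimated correlation, and not without WT 1 (0.0543) or at a filter of 5 FPKM (0.143), in a range of 0.004 to 0.421 over its alternatives.

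Neuronal markers had 1 of 9 tested members higher and 1 lower (1 and 1 adjusted over the list alone). Stmn2, a growth cone protein, rose from 29.7 to 55.5 FPKM and Gad1, which makes GABA, fell from 76.4 to 43.9 FPKM, a call that ended without CD38 KO 2 (0.0581). The neuronal list was not called (camera adjusted p = 0.77), while fry called it upward (0.0321, range over its alternatives 0.0321 to 0.912). Fibroblast and meningeal genes had 1 of 14 members higher, Igfbp2, and 4 lower (2 and 5 adjusted over the list alone). Islr fell from 411 to 146 FPKM and Thy1, a surface glycoprotein, from 457 to 334 FPKM, and Pdgfra and Ogn were the other lower members. The call of Thy1 ended with no filter (0.053, range over its alternatives 0.00226 to 0.053). The calls of Ogn and Igfbp2 ended in all 4 fits without 1 library (adjusted p up to 0.193 and 0.242) and that of Pdgfra without WT 2, CD38 KO 1 and CD38 KO 2 (up to 0.12), and the list was not called (camera adjusted p = 0.229, downward, median 0.02, and -0.21 to 0.11 without 1 library, mean -0.12). Among endothelial and pericyte genes limma called 0 of 4, also adjusted over the list alone, with 2 higher at an unadjusted p under 0.05 (camera adjusted p = 0.485). Sex-linked genes were lower in 2 of 5 tested members (4 lower adjusted over the list alone). The Y-linked Eif2s3y fell from 22.2 to 14.9 FPKM and Kdm5d from 7.09 to 5.00 FPKM, while Xist, transcribed from the inactive X chromosome, was at 27.1 FPKM in WT and 27.0 in CD38 KO. Cultures of both genotypes thus held RNA from both sexes. The calls of Eif2s3y and Kdm5d ended without WT 2, CD38 KO 1 and CD38 KO 2 (adjusted p up to 0.118 and 0.123). Camera called the sex-linked list (adjusted p = 0.0247, median -0.30), with adjusted p = 0.421 with an estimated correlation, and not without CD38 KO 1 (0.052) or at a filter of 5 FPKM (0.0677), in a range of 0.014 to 0.421 over its alternatives.

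Genes around Cd38 on chromosome 5 were compared with the rest of the genome, since a knockout allele can carry flanking sequence of the strain it was made in. Within 10 Mb of Cd38, 16 of 83 tested genes were called, 19.3%, against 1859 of 12981 elsewhere, 14.3% (odds ratio 1.43, Fisher's exact test, two-sided, p = 0.208). Within 20 Mb, a window that also holds Abhd1, 38 of 181 genes were called (odds ratio 1.60, Fisher's exact test, p = 0.0137). The p ranged from 0.0137 to 1 over its 17 alternatives, and without WT 1, WT 2, CD38 KO 1 and CD38 KO 2 the odds ratios were 0.84, 0.953, 0.857 and 0.543.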

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

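The fits on protein-coding genes only, with a crossed replicate block, without genes shared with the microglia list, and around Cd38 without Cd38 itself or under each gene-test setting were chosen after seeing the data, and the other settings before. No setting changed the sign of a called gene, and Cd38 was called in all 13 of its alternatives (adjusted p 0.000165 to 0.0154). The genes higher and lower numbered 430 and 312 with no filter, where more genes were tested, and 610 and 427 with a replicate block, which kept 1023 of the 1875 calls. A 2-fold limit left 259 and 101. Without a test, a 2-fold change with both libraries of one genotype above both of the other gave 262 and 105. Leaving out 1 library, which leaves fewer samples, gave 306 to 458 higher and 225 to 284 lower. Under the other settings the counts stayed within 1.5 times 1045 and 830, from 814 higher at a filter of 5 FPKM to 1208 with protein-coding genes only, and from 619 lower without trend to 945 with quantile normalization. The fit on protein-coding genes only called 921 lower. The crossed block called 1961 genes, among them 1733 of the 1875. The number of lists called ran from 8 at a filter of 5 FPKM to 17 with fry, and was 0 with an estimated correlation. The chemokine list turned from downward to upward with fry (0.0317, range over its alternatives 0.0317 to 0.913), and the cause was not tested. Genes around Cd38 had an odds ratio of 1.60 within 20 Mb (Fisher's exact test, p = 0.0137, range over its alternatives 0.0137 to 1), and the cause was not tested. Of 127 called named genes besides Cd38, 55 lost the call in at least 1 fit without 1 library and 50 in at least 1 other setting. A count-based test was not run, since the values are not counts. Depth limits Cd38 in CD38 KO to 2 fragments per library.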

Other observations

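All tests of explanations in this part were chosen after the results were seen, as were the genes named here that the report does not name.

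Among the 20 genes of highest mean FPKM, 5 were lower, 1 was higher and 14 were not called, Apoe among the latter at 5151 FPKM in WT and 5092 in CD38 KO. Cst3, the protease inhibitor cystatin C, fell from 4375 ± 50.7 to 2258 ± 9.93 FPKM (SD, n = 2 each), and Mt2 fell from 2372 to 1410 FPKM. Lcn2, an iron-binding lipocalin, was lower at 12943 against 17267 FPKM, and Spp1, C3 and Mt3 were called too, Mt3 as the higher gene. Those 4 calls ended in all 4 fits without 1 library (adjusted p up to 0.174, 0.111, 0.23 and 0.2).

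The next 7 genes belong to no list fixed beforehand and stand for no gene class. Slco1c1, a thyroid hormone carrier of brain cells, fell from 38.1 to 11.2 FPKM while its relative Slco1a5 rose from 11.6 to 73.3 FPKM. Socs3, an inhibitor of cytokine signalling, fell from 132 to 59.3 FPKM, the potassium channel partner Kcnip1 from 27.7 to 7.61 FPKM and the vessel growth factor Angpt1 from 40.6 to 18.6 FPKM. The translation factor Eef1a2 fell from 91.7 to 26.6 FPKM. C1ql1, a secreted synapse organizer, fell from 42.9 to 20.8 FPKM. All 7 were called in all 4 fits without 1 library.

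The rise of microglia and macrophage genes was tested against 2 explanations. Scaling between libraries is argued against, since the list median stayed at 2.23 or more under quantile normalization and median-of-ratios scaling. More cells of the macrophage lineage in the CD38 KO cultures and a change within such cells cannot be told apart, since either would raise the 19 of 20 tested members called higher, with Lyz2 at 402 FPKM, Laptm5 at 65.2 and Fcer1g at 60.4 in CD38 KO. The protocol's shaking for 12 h is a step that removes such cells, 17 of the 20 members were at 1 FPKM or more in WT, and 6 are in another list. The ratios ran from 3.89 to 12.1 in the 17 members called in all 4 fits without 1 library and were lower in the other 2 called members, a wider spread than the 2-fold set for more cells alone. An effect of Cd38 on either stays open.

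Changes of 2-fold or more fell on 42 of 338 tested pseudogenes, 12.4%, against 2.55% of other genes (odds ratio 5.41, Fisher's exact test, two-sided, p = 3.32e-16), with 12 higher and 30 lower. Such a change also needed both libraries of one genotype above both of the other, but no limma call. Low FPKM by itself is argued against, since the highest of 10000 draws of other genes matched on mean FPKM held 31. The draws were not matched on transcript length, so a low number of fragments is not set aside by them. A segment of another strain within 20 Mb of Cd38 does not hold these pseudogenes, as 0 of the 42 lie there. That window held only 181 of the 13064 tested genes, so the count cannot tell whether such a segment is present. Reads shared between a gene and its near copy, placed differently in the 2 genotypes, may account for part of the pseudogene changes. The parent's log2 change had the opposite sign in 9 of 9 pairs (exact sign test p = 0.00391), 6 of them with a called parent. For the other 33 changed pseudogenes no parent was compared. In 7 of the pairs the parent changed by more FPKM than its pseudogene, as Nsa2 from 40.2 to 53.1 FPKM beside Nsa2-ps1 from 5.92 to 0.281 FPKM. Rps26-ps1 went from 72.9 to 2.21 FPKM beside Rps26 from 188 to 221 FPKM. FPKM is scaled to transcript length, so these sizes cannot tell whether shared reads are the whole cause. The strains are not given in the labels, so a strain difference elsewhere in the genome, which Cwc22 would also reflect, stays open as untested.

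The lower Sparcl1 level was tested against 2 explanations. Dilution of astrocyte RNA as the whole cause is argued against. The astrocyte identity list had a median log2 change of -0.18 (SD 0.358) against -0.66 for Sparcl1. A partial share of dilution in the fall of Sparcl1 is not set aside by these values. Scaling is argued against as well, since the value closest to 0 under quantile normalization and median-of-ratios scaling was -0.67. An effect of losing CD38 and a strain difference at Sparcl1, which lies on the same chromosome as Cd38, both stay open as untested. Gbp10, which fell 24.6-fold, lies closer to Sparcl1 on that chromosome than Cd38 does. Its position is 105215699 to 105239533, beside 104079111 to 104113733 for Sparcl1. Of 9 tested Gbp genes, 4 were lower and 1 was higher. Among the lower ones, Gbp4, from 5.79 to 1.48 FPKM, and Gbp9, from 20.9 to 9.88 FPKM, also lie on chromosome 5. The call of Gbp9 ended without CD38 KO 2. Whether a local strain difference lowered both Gbp10 and Sparcl1 was not tested.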
